A study of Mus musculus with 4 samples.

How the data were processed

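Single-nucleus RNA libraries of the kidney of female MRL/lpr and C57BL/6 mice aged 6 and 10 weeks were used, 1 library for each strain and age. Per the labels' protocols, nuclei were taken from an iodixanol gradient and loaded for droplet-based 3' sequencing with poly-dT priming. The deposited files hold 1 count matrix per library, and each value is a count of UMIs per gene and barcode, made by the authors with Cell Ranger. The version is 5.0.0 per the file headers and 3.1.0 per the submitters' processing notes. Barcodes were already called by the authors, and the rule was not stated. The matrices list 25636 genes, of which 25585 gene IDs match GENCODE mouse release 21. The genome build, and whether intronic reads were counted, are not given in the sources used here. Malat1, Neat1, Meg3, Xist and H2-L are not in the gene list, so Xist could not be used to check sex. Of the gene symbols, 27 are shared by 2 or more gene IDs, and these genes were kept apart by ID. Where near-identical gene copies exist, counts may be split between them or lost, and a difference in sequence between strains may change what is counted. Raw reads were not analysed here.

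Lists of genes, markers, filters, comparisons and the rule for naming genes were fixed before the data were examined. Barcodes with fewer than 200 genes or more than 10% mitochondrial UMIs were left out. Doublets were marked in each library with Scrublet as run in scanpy 1.11.5, at an expected rate of 0.8% per 1000 barcodes. The automatic threshold marked none in MRL/lpr 6 weeks, so there the barcodes with the highest scores, at that expected rate, were marked. In this way 702 barcodes of MRL/lpr 6 weeks, 871 of C57BL/6 6 weeks, 478 of MRL/lpr 10 weeks and 808 of C57BL/6 10 weeks were left out. Of 39074 barcodes 35622 were kept. The kept nuclei held 6586177, 5779425, 5822401 and 5710379 UMIs in the same order, with medians of 692, 561, 625 and 568 UMIs and 565, 464, 512 and 468 genes. Libraries differed in the lowest number of UMIs of a barcode, which was 308 in MRL/lpr 6 weeks and 209 in C57BL/6 6 weeks. No correction for free RNA was made in the main analysis.

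The 4 libraries were clustered together without integration. Counts were scaled to 10000 per barcode and log-transformed, and 3000 variable genes were chosen within libraries and combined. Mitochondrial, ribosomal, MHC, immunoglobulin, haemoglobin, sex-linked, early response and circadian genes were left out of this choice. With 40 principal components, 15 neighbours and Leiden resolution 1, 20 clusters formed. Markers were fixed beforehand, but the rule for naming from them was not. Among classes with at least 3 markers enriched at least 3-fold over the median cluster, a cluster took the name of the one with most markers among its 10 leading genes, and then of the one with most enriched markers. It stayed unnamed if another class had more markers among them. With none of its own among them it was named only if at least 50% of the markers of the class were enriched, at least 2 times as many as of any other class, and its nuclei had at least 1/3 of the median UMIs of their libraries. Clusters 0, 2, 4 and 13 were named in this way from 10 to 12 enriched markers, with at most 1 of any other class. Cluster 9, with 976 nuclei, was named distal convoluted tubule from 4 enriched markers, 3 of them leading, although 5 connecting tubule markers were enriched, 2 of them leading (Calb1 and Slc8a1), so that class also holds connecting tubule. The proximal tubule-like class joined clusters 0, 1, 2, 4, 13 and 14. Cluster 0 was led by Rnase4, Ang4 and Cacna2d2, cluster 1 by Pik3c2g, Slc5a12 and Ttr, cluster 4 by Cyp2d12, Cyp4a14 and Cyp4a10, and cluster 13 by interferon genes, so these genes and the strain makeup of the clusters are not independent. The cluster named mesangial by its fixed markers held 6 of them (Itga8, Gata3, Piezo2, Serpine2, Pdgfrb and Fhl2) but was led by Ren1 and also held smooth muscle markers, and it is called mural-like. The clusters were made with all libraries, and no class was checked by another method. Shares were given with exact binomial intervals over the kept nuclei.

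UMIs were summed over the nuclei of a class in each library and scaled to CPM. Genes with at least 50 UMIs over the 4 libraries of a class were compared. The log2 ratio of MRL/lpr over C57BL/6 at each age and of 10 over 6 weeks in each strain was given with the conditional exact binomial 95% interval, and that of share ratios likewise from counts. With 1 library per group no test was run. Ratios with 0 UMIs on one side are given as at least the ratio against 3 UMIs, the number that a count of 0 allows. A prior of 0.5 UMI was meant for ranking only, but it is also in the log2 ratios of genes, the list medians, the strain differences of age ratios and the counts of genes at least 2-fold apart. Folds and the intervals of gene ratios hold no prior. Without the prior and with 0 set at 3 UMIs, 292 genes would be higher and 206 lower at both ages in the proximal tubule, 67 and 54 in macrophage, 4 and 5 in mural, 31 and 48 in podocyte and 68 and 73 in endothelium classes. For age in the proximal tubule 39 and 19 would be. Medians of described lists would then move by at most 0.113, and 3 of 108 by over 0.05. A strain difference of age ratios with a count of 0 is given as a bound without the prior. Genes at least 2-fold apart in the same direction at both ages were counted, and genes at least 2-fold apart in opposite directions beside them.

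Named genes are the first 8 higher and first 8 lower of the genes at least 2-fold apart in the same direction at both ages, ranked by the smaller of the 2 ratios, with 10 and 10 in the proximal tubule. For age the first 5 in each direction in the proximal tubule were named, and for the strain difference of the age ratio the 5 largest in each direction in macrophage-like and mural-like nuclei whose intervals exclude 0. Up to 4 members with most UMIs of each described list and the label check genes were also named, and unnamed predicted genes were counted only. A few genes that this rule or the lists select are not reported here, and they remain in the counts and medians. Other genes, namely Havcr1, Arntl, Npas2, Dbp, Nr1d1, Acox2, Cyp4a10, Cyp4a14 and Fabp1 in the proximal tubule, and those of the other observations, were chosen after their values were seen, and so were the lists described among the 30 that were fixed. Each list was summarised, where at least 3 members could be compared, by the median log2 ratio with an interval from 1000 Poisson resamples, and by its percentile among 10000 random lists of the same size matched on expression in 20 bins.

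The counting and naming steps were tested on simulated data. Libraries drawn with no strain difference gave means of 1.4, 9.15, 0.2, 1.35 and 3.2 genes at least 2-fold apart in the same direction at both ages in proximal tubule, macrophage, mural, podocyte and endothelium classes, from 11802, 4334, 169, 1248 and 5559 compared genes. Of genes given a 3-fold difference, 97.0% of 67, 78.5% of 65, 66.7% of 18, 86.2% of 65 and 86.4% of 66 were found in the same order of classes, and of those given a 4-fold difference 98.5% of 66, 97.0% of 66, 93.3% of 15, 97.0% of 66 and 95.4% of 65. A 1.5-fold difference was named in 0% of 67, 0% of 65, 0% of 16, 1.59% of 63 and 2.99% of 67 genes. Intervals held the true value in 95.9, 97.1, 97.0, 97.2 and 96.5% of cases. These simulations hold counting error only.

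Alternatives fixed in advance were a minimum of 500 genes per barcode, no limit or a limit of 2% on mitochondrial UMIs, doublets kept, each library clustered on its own, resolution 0.5, scaling by the median of ratios or by TMM in edgeR 4.0.16, minima of 20 or 200 UMIs per gene, nuclei thinned to 500 UMIs, and proximal tubule markers and free RNA genes left out of other classes. Added after the data were seen were a common minimum of 308 UMIs, other-class nuclei with UMIs of 3 or more proximal tubule markers left out, macrophage-like sub-clusters in which macrophage markers were seen at least 2 times as often as those of any other class, and genes at higher CPM in the proximal tubule left out of other classes. Genes shared by many classes were set against tubule RNA with proximal tubule markers of at least 50 UMIs in the proximal tubule of the library, also after the data were seen, as was the comparison of list medians over the members left without tubule-marker nuclei. To find genes at higher CPM in the proximal tubule, the UMIs of each class were pooled over the 4 libraries. Sub-clusters used 1000 variable genes and 15 components. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9, matplotlib 3.10.9 and R 4.3.3.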

Results

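Nuclei from the kidney cortex of female mice of 2 strains were profiled at 2 ages by droplet-based 3' RNA sequencing. MRL/lpr mice, which carry a mutation of the death receptor gene Fas and develop lupus-like nephritis, were set against C57BL/6 mice at 6 and at 10 weeks. No MRL mice with intact Fas were among the groups. The Fas mutation, other differences between the strains and disease therefore cannot be told apart in any strain ratio. The series title names the effect of macrophages on mesangial cells in lupus nephritis as its subject. There were 4 groups with 1 library each, so no difference has a replicate check, no test between groups was run, and all values describe these 4 libraries. The strain ratio at 6 weeks and that at 10 weeks share no library, and genes lying in the same direction at both ages are reported on that basis. Intervals are 95% intervals and cover counting error only.

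The libraries held 9365 barcodes in MRL/lpr 6 weeks, 10182 in C57BL/6 6 weeks, 9889 in MRL/lpr 10 weeks and 9638 in C57BL/6 10 weeks, with 7660682, 6847593, 6466973 and 6754055 UMIs. Values given as a run of 4 follow this order of libraries throughout. The nuclei were shallow, with a median of 714, 589, 623 and 595.5 UMIs. The barcode with the fewest UMIs held 308, 209, 175 and 228 of them, so the MRL/lpr 6 week library had the highest minimum. After filtering 8662, 9139, 9012 and 8809 nuclei remained. H2-Ea, an MHC class II gene that mice of the H-2b haplotype such as C57BL/6 do not transcribe, had 49 and 38 UMIs in the MRL/lpr libraries (7.44 and 6.53 CPM, UMIs scaled to 1000000) and 0 in both C57BL/6 libraries, where 0 allows up to 0.519 and 0.525 CPM. Fas had 220, 175, 182 and 124 UMIs, but counts over the whole gene do not locate the lpr insertion and check nothing. The 4 Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y summed to 2, 4, 3 and 3 UMIs, as the labels name females.

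Cell class makeup differed between the strains. Proximal tubule-like nuclei made up 61.4, 43.3, 59.3 and 46.5% of the kept nuclei, a share 1.42 times (1.36 to 1.48) that of C57BL/6 at 6 weeks and 1.28 times (1.22 to 1.33) at 10 weeks. Endothelium-like nuclei were the reverse, at 5.33, 14.2, 5.65 and 9.86%, with ratios of 0.376 (0.337 to 0.418) and 0.573 (0.512 to 0.639). Podocyte-like nuclei, the filtering epithelium of the glomerulus, were fewer in MRL/lpr at both ages, at 1.18, 1.82, 1.60 and 2.38%, with ratios of 0.648 (0.502 to 0.835) and 0.670 (0.538 to 0.833). Distal convoluted tubule-like nuclei also made up less of the MRL/lpr libraries, at 7.47, 12.5, 6.67 and 12.8%. These shares may also depend on losses in the preparation, which were not tested, and on the UMI minimum of each library. A minimum of 308 UMIs in all 4 libraries gave endothelium ratios of 0.935 at 6 weeks and 0.561 (0.470 to 0.668) at 10 weeks. It was 0.668 (0.575 to 0.775) at 6 weeks when nuclei of other classes with 3 or more proximal tubule markers were left out as well. With at least 500 genes per nucleus, the podocyte ratios were 1.62 and 1.88 and the proximal tubule ratio at 6 weeks was 0.951. The endothelium share at 6 weeks was then higher in MRL/lpr, in a cluster mixed with macrophage genes.

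Macrophage-like nuclei made up 2.60, 1.2, 2.64 and 2.42% of the kept nuclei. Their share in MRL/lpr was 2.16 times (1.71 to 2.74) that in C57BL/6 at 6 weeks and 1.09 times (0.904 to 1.32) at 10 weeks, and in C57BL/6 it was 2.01 times (1.59 to 2.55) as high at 10 as at 6 weeks. In this class 71.6, 31.8, 35.7 and 35.2% of the nuclei held UMIs of 3 or more proximal tubule markers, and with such nuclei left out the ratio at 6 weeks was 0.932. Mural-like nuclei, which carried mesangial, smooth muscle and renin cell markers, numbered 28, 89, 50 and 49, or 0.323, 0.974, 0.555 and 0.556%. Their share ratio between strains was 0.332 (0.209 to 0.513) at 6 weeks and 0.997 (0.659 to 1.51) at 10 weeks, and 0.612 at 6 weeks with a minimum of 308 UMIs in all libraries. Fibroblast-like nuclei followed the same course, with ratios of 0.204 (0.169 to 0.244) and 0.721 (0.602 to 0.864). The shares of thick ascending limb-like, principal cell-like and intercalated cell-like nuclei lay between 0.822 and 1.16 times those of C57BL/6 at both ages.

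**Figure D1:**
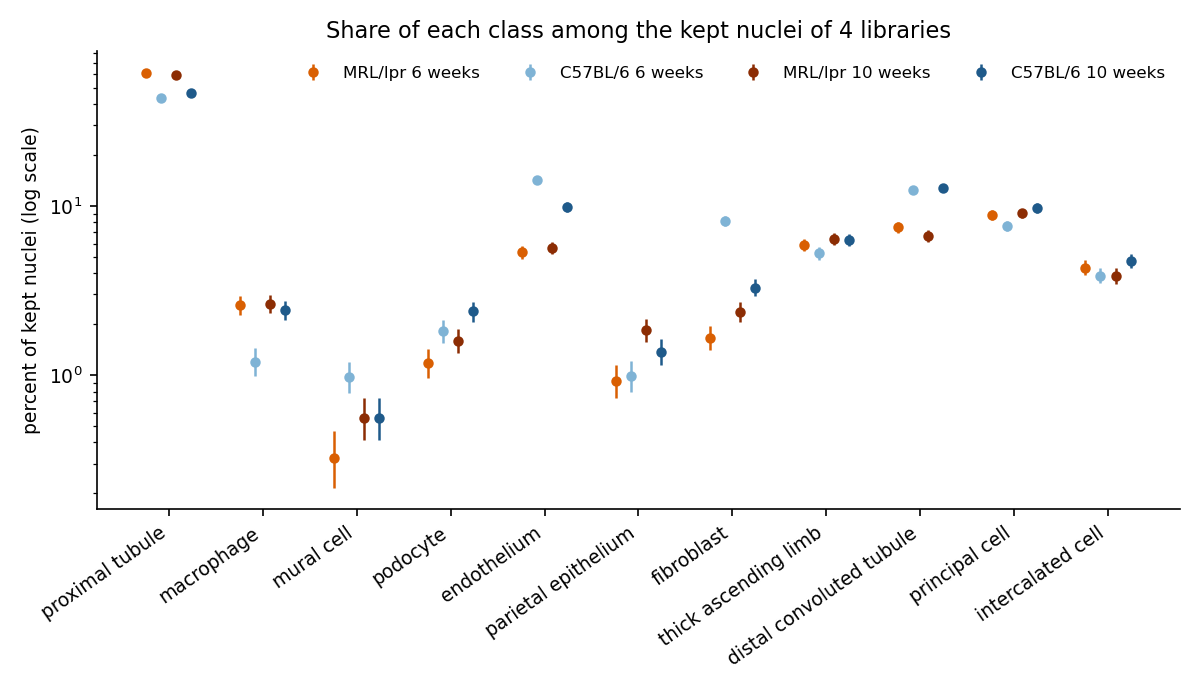
Percent of kept nuclei in each class (y axis, log scale) in the 4 libraries, with exact binomial 95% intervals as error bars for counting error only. Proximal tubule-like shares lie higher in both MRL/lpr libraries (61.4 and 59.3%) than in both C57BL/6 libraries (43.3 and 46.5%), and endothelium-like shares lie lower.

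Between strains, 287 genes were at least 2-fold higher and 203 lower in MRL/lpr at both ages among 11789 genes of the proximal tubule, the class with most compared genes. These made up 4.16% of its genes, against 6.14% in podocyte-like and 5.03% in mural-like nuclei, while 39 were at least 2-fold apart in opposite directions. The scavenger receptor gene Colec12 (ENSMUSG00000036103) was 176-fold (147 to 212) higher in MRL/lpr at 6 weeks and 913-fold (578 to 1541) at 10 weeks, from 26716, 122, 19493 and 18 UMIs. The thyroxine and retinol carrier transthyretin, Ttr (ENSMUSG00000061808), was 213-fold (90.7 to 656) and 113-fold (38.3 to 551) lower. Interferon gamma response and antigen processing genes were higher in MRL/lpr at both ages, and genes of fatty acid oxidation were lower. Clusters 0, 2 and 13 held 56.7, 31.1 and 4.27% of the class in MRL/lpr 6 weeks and 48.3, 32.4 and 6.92% in MRL/lpr 10 weeks, whereas clusters 1 and 4 held 62.9 and 24.1% of it in C57BL/6 6 weeks and 52.2 and 38.6% in C57BL/6 10 weeks. Simulated libraries with no strain difference, which hold counting error only, gave a mean of 1.4 such genes in this class.

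Several genes were close to 0 UMIs in 1 strain. Ang4, a ribonuclease of the angiogenin family, had 251, 0, 603 and 1 UMIs and was at least 67.2-fold higher in MRL/lpr at 6 weeks and 509-fold (90.9 to 20120) at 10 weeks. Prss48, a serine protease gene, was 434-fold (77.5 to 17169) and at least 114-fold higher. Ifnk, which encodes interferon kappa, had 126, 0, 115 and 0 UMIs, at least 33.7-fold and at least 32.3-fold higher. The calcium channel subunit gene Cacna2d2 was at least 55.2-fold and 207-fold (36.9 to 8227) higher. Mybphl, Clca4a, Serpina3b, Asz1 and Lrrc9 had 0 UMIs in both C57BL/6 libraries and were at least 13.4-fold higher at 6 weeks and at least 14.1-fold at 10 weeks. Among the genes lower in MRL/lpr, the cytochrome P450 gene Cyp2f2 was 77.8-fold (21.1 to 649) and 58.1-fold (15.7 to 486) lower and Nxpe3 was 22.5-fold (12.3 to 45.8) and 30.9-fold (16.6 to 65.3) lower. Plcl2, a phospholipase C-like gene, was 19.0-fold (11.7 to 33.2) and 14.5-fold (9.26 to 23.8) lower, and the methyltransferase gene Inmt 14.4-fold (7.58 to 30.9) and 48.4-fold (23.2 to 122). Lrit3 (0, 30, 0 and 28 UMIs), Rab6b (0, 35, 1 and 41), Trim12a (2, 40, 0 and 34), Serpina1a (0, 13, 2 and 38) and the histidine breakdown gene Amdhd1 (1, 16, 0 and 42) were lower as well. Ang4 and Cacna2d2 were among the leading genes of cluster 0, and Ttr among those of cluster 1. Serpina1a, Serpina3b, Ang4 and Trim12a belong to families of closely related genes, which the deposited counts may not separate. Unnamed predicted genes made up 46 of the higher and 22 of the lower genes.

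**Figure D2:**
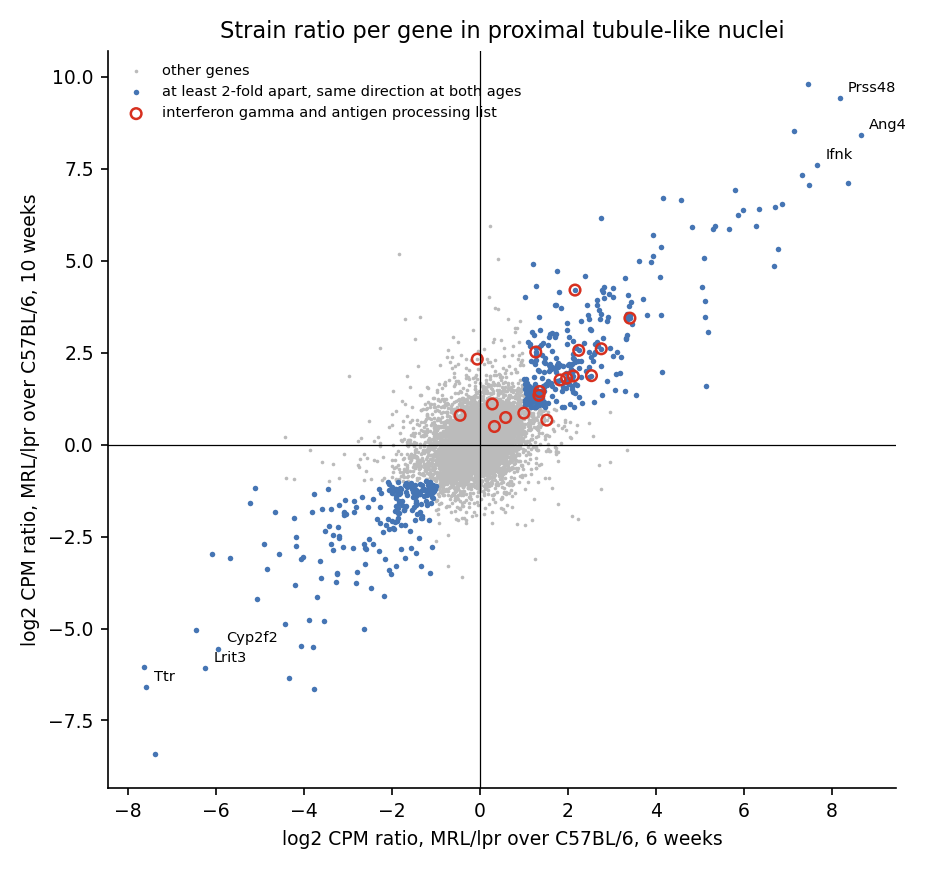
Log2 CPM ratio of MRL/lpr over C57BL/6 in proximal tubule-like nuclei at 6 weeks (x axis) and 10 weeks (y axis), with 1 point per gene and 1 library per group. The 287 genes higher and 203 genes lower by at least 2-fold at both ages lie in the upper right and lower left corners.

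Of the 24 genes of the interferon gamma and antigen processing list, 18 had enough UMIs in the proximal tubule; 16 were higher in MRL/lpr at both ages and 11 were at least 2-fold higher at both. The median log2 strain ratio was 1.44 (1.11 to 1.96) at 6 weeks and 1.78 (1.46 to 1.99) at 10 weeks, at percentile 100 of 10000 random lists matched on expression, and 1.55 and 1.79 without the prior of 0.5 UMI. The immunity-related GTPase genes Iigp1 (log2 3.41 and 3.44) and Irgm2 (1.82 and 1.76) had 112, 8, 327 and 25 and 160, 36, 286 and 71 UMIs. Tapbp, which loads peptides onto MHC class I, lay at 1.00 and 0.86, and the transcription factor gene Irf8 at 0.28 and 1.1. With age the list's median was 0.91 (0.65 to 1.07) higher in MRL/lpr and 0.52 (0.18 to 0.92) in C57BL/6, and 12 members were higher at 10 weeks in both strains. Iigp1, Irgm2, Igtp, Gbp6 and Irf1 also led cluster 13, which held 227, 33, 370 and 44 nuclei. The type I interferon list stood less far apart: of 16 members 8 were higher and 5 lower at both ages, with medians of 0.09 (-0.14 to 0.32) at percentile 87.5 and 0.39 (0.06 to 0.62) at percentile 95.3. Among its members with most UMIs, Ifi27 (0.16 and 0.46) and Stat2 (0.51 and 1.16) were higher and Ddx58 (-0.07 and -0.04) lower in MRL/lpr at both ages.

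**Figure D3:**
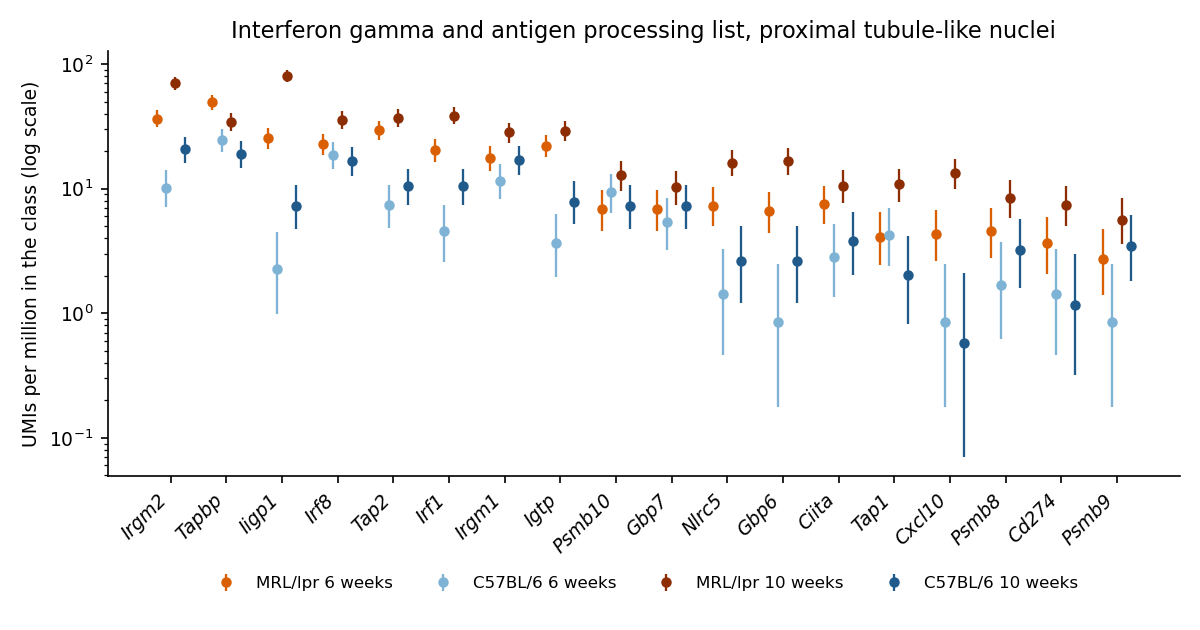
CPM (y axis, log scale) of the members of the interferon gamma and antigen processing list in proximal tubule-like nuclei of the 4 libraries, with exact Poisson 95% intervals as error bars for counting error only. Values of MRL/lpr lie above those of C57BL/6 at the same age in 16 of 18 members at both ages.

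MHC class II genes, which differ in sequence between the strains, were higher in MRL/lpr proximal tubule in 5 of 6 members at both ages, with medians of 1.16 (0.72 to 1.47) and 0.69 (0.47 to 0.89) at percentiles 100 and 99.0. Cd74, the invariant chain of class II molecules, had 589, 84, 792 and 445 UMIs, and H2-Ab1 135, 48, 184 and 115. All 6 were higher at 10 than at 6 weeks in both strains, with medians of 0.76 in MRL/lpr and 1.06 in C57BL/6. Of 8 complement genes 5 were higher in MRL/lpr at both ages and 1 lower, with medians of 0.22 (-0.07 to 0.56) and 0.69 (0.28 to 1.01) at percentiles 91.8 and 98.8. C4b had 96, 7, 108 and 5 UMIs, Cd59a 139, 44, 104 and 41, and Cfb, a component of the alternative pathway, 489, 313, 353 and 228. In the tubular injury list 7 of 15 members were higher and 2 lower at both ages, with medians of 0.43 (0.15 to 0.63) at percentile 99.6 and 0.20 (-0.05 to 0.61) at percentile 76.2. Spp1, which encodes osteopontin, was higher by 0.79 (0.72 to 0.86) and 0.84 (0.75 to 0.93). Havcr1, which encodes the injury marker KIM-1 and was chosen after its values were seen, had 25, 0, 36 and 0 UMIs.

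Fatty acid oxidation and PPAR genes were lower in MRL/lpr proximal tubule in 18 of 28 members at both ages and higher in 2. The medians were -0.43 (-0.48 to -0.34) and -0.56 (-0.71 to -0.46), both at percentile 0. At least 2-fold lower at both ages, and picked after their values were seen, were Acox2 (121, 366, 200 and 447 UMIs), the fatty acid hydroxylase genes Cyp4a10 (327, 955, 246 and 825) and Cyp4a14 (1154, 2763, 385 and 2302), and the fatty acid binding protein gene Fabp1 (5, 24, 2 and 31). The regulator genes Ppara (-0.57 and 0.32) and Ppargc1a (-0.46 and 0.24) were lower at 6 and higher at 10 weeks, while Slc27a2 (-0.30 and -0.14) and Acaa1b (-0.43 and -0.91) were lower at both. Nuclear-encoded respiratory chain genes were lower at both ages in 28 of 36 members, with medians of -0.23 (-0.26 to -0.17) and -0.48 (-0.53 to -0.43) (Cox6c -0.40 and -0.80), and 28 were lower at 10 than at 6 weeks in both strains. At 10 weeks the cytoplasmic ribosomal protein genes (-0.44) and the mitochondrially encoded genes (-1.33) of the class lay lower in MRL/lpr as well. Transport and reabsorption genes went both ways, 6 higher and 13 lower of 31, with medians of -0.08 and -0.06. Within them the lactate transporter gene Slc5a12 (-1.59 and -0.46) and the bicarbonate transporter gene Slc4a4 (-0.36 and -0.20) were lower, and the phosphate transporter gene Slc34a1 lay at -0.48 and -0.03. In the sex-biased list 5 of 10 members were higher and 2 lower, with medians of 0.40 (0.28 to 0.57) and 0.02 (-0.18 to 0.15). Kap, a gene under androgen control, had 4642, 1966, 1986 and 3055 UMIs, and Cyp4b1 1786, 548, 1514 and 195.

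Circadian clock genes stood at different phases in the libraries, and 13 of 16 had opposite strain ratios at 6 and 10 weeks. Arntl, which encodes the clock activator BMAL1, had 712, 280, 122 and 471 UMIs and Npas2 693, 232, 98 and 714. Dbp (50, 45, 270 and 26 UMIs) and Nr1d1 (13, 52, 172 and 23), a target and a repressor of that activator, went the other way. Arntl, Npas2, Dbp and Nr1d1 were chosen after their values were seen; of the clock genes with most UMIs, Hlf lay at 0.05 and -0.63, Tef at -0.85 and 0.02, and Clock at 0.06 and -0.11. The list's medians were -0.04 (-0.16 to 0.14) and -0.37 (-0.49 to -0.28). Mitochondrially encoded genes moved with the same libraries: all 11 members were higher in MRL/lpr at 6 weeks and lower at 10 weeks, with medians of 0.39 (0.30 to 0.52) and -1.33 (-1.46 to -1.15), and mt-Co3 had 2962, 1817, 1059 and 1816 UMIs; their median age ratio was -1.68 in MRL/lpr and 0.09 in C57BL/6. For 35 cytoplasmic ribosomal protein genes the medians were 0.26 (0.24 to 0.33) and -0.44 (-0.49 to -0.39), with 2 members lower at both ages and Rps19 at 0.61 and -0.15.

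**Figure D4:**
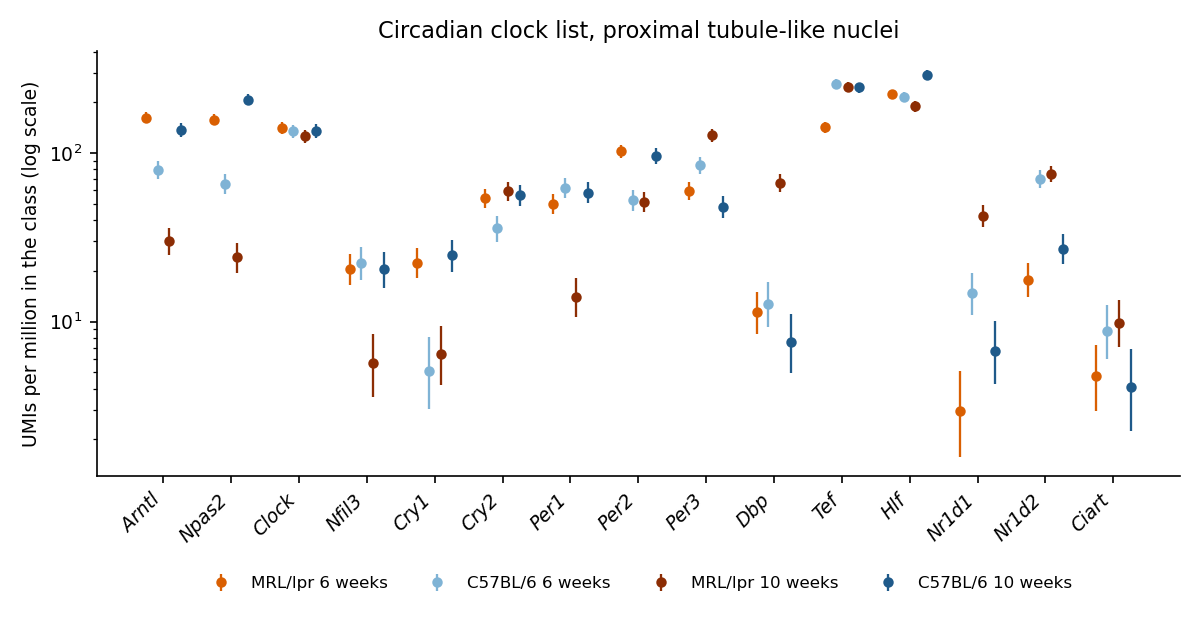
CPM (y axis, log scale) of circadian clock genes in proximal tubule-like nuclei of the 4 libraries, with exact Poisson 95% intervals as error bars for counting error only. Arntl and Npas2 lie lowest and Dbp and Nr1d1 highest in MRL/lpr 10 weeks.

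Between 6 and 10 weeks the proximal tubule showed fewer shared differences: 40 genes were at least 2-fold higher and 19 at least 2-fold lower at 10 weeks in both strains, against 54 in opposite directions. Cyp27b1, which encodes the enzyme that makes active vitamin D, was 119-fold (20.9 to 4731) higher in MRL/lpr and 6.17-fold (3.67 to 11) higher in C57BL/6, from 1, 17, 110 and 102 UMIs. The carbonic anhydrase gene Car3 was 5.94-fold (2.46 to 17.3) and 4.55-fold (2.95 to 7.26) higher, and Iigp1 3.15-fold (2.54 to 3.94) and 3.21-fold (1.40 to 8.24) higher. Cbr3 had 3, 8, 10 and 45 UMIs and Igha, the constant region of immunoglobulin A made by plasma cells, 1, 0, 82 and 3, but in C57BL/6 its 3 UMIs against 0 give no fold, so it is among the 40 by the prior of 0.5 UMI alone; without the prior 39 were higher. The stress response gene Gadd45g was 6.10-fold (5.28 to 7.07) lower at 10 weeks in MRL/lpr and 2.86-fold (2.5 to 3.28) lower in C57BL/6. Klf2 was 2.78-fold (1.27 to 6.72) and 2.64-fold (1.40 to 5.27) lower, Noxred1 2.87-fold (1.37 to 6.57) and 2.43-fold (1.13 to 5.67), and Cyp2j13 2.68-fold (1.22 to 6.49) and 5.84-fold (1.70 to 30.9). Cox6a2 had 12, 33, 2 and 3 UMIs.

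In the macrophage-like class 54 genes were at least 2-fold higher and 54 at least 2-fold lower in MRL/lpr at both ages among 4323, with 36 in opposite directions. Genes of the MHC stood at both ends: H2-Ea was at least 2.83-fold and at least 11-fold higher in MRL/lpr, and H2-Q7 (ENSMUSG00000060550), a nonclassical class I gene, 36.2-fold (8.41 to 326) and 25.7-fold (6.83 to 217) lower. Nlrp1b, an inflammasome sensor gene that varies between strains, was 37.0-fold (11.2 to 192) and 3.76-fold (1.40 to 12.7) lower. With UMIs pooled over the 4 libraries, 34 of the 54 higher and 26 of the 54 lower genes had higher CPM in the proximal tubule than in this class. The libraries contribute to the 2 classes in unlike shares, so a difference between strains can change this count. Simulated libraries with no strain difference, which hold counting error only, gave a mean of 9.15 genes in this class. The class held 225, 110, 238 and 213 nuclei with medians of 1161, 491.5, 429 and 481 UMIs, and Slc34a1, a proximal tubule transporter gene, was seen in 73.3, 40.9, 45.8 and 43.2% of them, against 97.8, 98.2, 98.7 and 96.4% of proximal tubule-like nuclei and 22.5, 18.1, 31.2 and 20.5% of podocyte-like nuclei, whose medians were 509, 435, 600.5 and 446 UMIs. Of these nuclei 33, 24, 90 and 60 lay in a sub-cluster led by macrophage markers, and the others in sub-clusters led by other genes, among them those of T cells, dendritic cells, endothelium and tubules. Without nuclei that held 3 or more proximal tubule markers, 13 of 536 compared genes were at least 2-fold apart in the same direction (2.43%, against 2.5% with them) and 6 in opposite directions.

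Further genes higher in MRL/lpr macrophage-like nuclei were Colec12 (2259, 1, 514 and 6 UMIs), Ang4 (39, 0, 18 and 0), Angptl7 (66, 1, 10 and 0) and the calcium channel gene Cacna1a, which was 9.75-fold (1.67 to 393) and 18.1-fold (6.69 to 68.5) higher. Stam2, an endosomal sorting gene, was 7.21-fold (2.75 to 26.8) and 7.75-fold (3.25 to 22.4) higher. With UMIs pooled over the 4 libraries, the metallothionein gene Mt2 had higher CPM in the proximal tubule. So did Pik3c2g, Cyp4a10, Cyp4a14, Dmac2 and Cyp2d12 on the lower side, where Cyp4a14 was 4.52-fold (2.65 to 7.68) and 4.72-fold (2.30 to 10.9) lower. Within the C57BL/6 libraries Dmac2 stood at 93.4% of its proximal tubule CPM at 6 weeks and 124% at 10 weeks. The CPM of Colec12 in this class was 94.3 and 67.4% of that in the proximal tubule at 6 and 10 weeks in MRL/lpr, where that of proximal tubule markers reached 104 and 73.6%. In the same libraries Stam2 stood at 87.4 and 86.8%. Rgcc was 4.82-fold (1.98 to 11.7) and 3.68-fold (1.49 to 10.9) lower.

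Macrophage gene groups lay on opposite sides at the 2 ages. Kidney-resident macrophage genes had a median log2 strain ratio of -1.12 (-1.36 to -0.87) at 6 weeks, at percentile 0, and 0.27 (0.03 to 0.54) at 10 weeks, at percentile 96.9; 2 of 10 members were lower at both ages and 8 went both ways. The complement initiator genes C1qa (-1.29 and 0.81), C1qb (-1.67 and 0.41) and C1qc (-1.08 and 0.99) were lower at 6 and higher at 10 weeks, with 321, 162, 342 and 239 UMIs for C1qa. MHC class II genes followed, with medians of -0.83 (-0.98 to -0.72) and 0.67 (0.52 to 0.81) over 6 members; Cd74 lay at -0.90 and 0.53. Interferon gamma genes had medians of -0.85 (-1.33 to -0.17) and 1.15 (0.63 to 1.46) over 7 members, 1 of them higher at both ages, with Irf8 at -1.43 and 0.90 and the class II transactivator gene Ciita at -0.74 and 1.21. Infiltrating monocyte genes had medians of -0.34 (-0.69 to 0.16) and 0.89 (0.56 to 1.41) over 4 members, with the lysozyme gene Lyz2 (195, 45, 400 and 100 UMIs) at -0.17 and 2.29 and the phagocyte oxidase gene Cybb at -0.89 and 1.56. Genes of tubule RNA moved against them, with medians of 0.33 (0.10 to 0.59) and -0.28 (-0.41 to -0.13) over 10 members, and Gpx3 at 0.70 and -0.17. Without nuclei that held 3 or more proximal tubule markers, the medians at 6 and 10 weeks were -0.15 and 0.25 for resident genes, 0.28 and 0.58 for class II, 0.33 and 0.66 for interferon gamma, and 0.45 and 1.07 for monocyte genes. Of these lists 8, 6, 3 and 3 members were left, which in all nuclei lay at -1.22 and 0.49, -0.83 and 0.67, -0.74 and 0.90, and -0.52 and 1.56. In the sub-clusters richest in macrophage markers they were -0.50 and 0.00998 for resident genes and -0.22 and 0.30 for class II. There monocyte genes lay at 0.11 and 0.66 over 3 members, and 0.11 is within the main interval of -0.69 to 0.16. With a common UMI minimum in all libraries, monocyte genes lay at 0.29 and 0.91, with 0.29 above that interval. Resident genes then stayed lower at 6 weeks (-0.87 and 0.42), as did class II (-0.40 and 0.70) and interferon gamma genes (-0.43 and 1.07).

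The age ratio of some genes differed between strains in macrophage-like nuclei. The monocyte chemokine gene Ccl12 had 19, 9, 43 and 8 UMIs, a difference of log2 age ratios of 3.88 (2.34 to 5.42). It was 4.44 (1.82 to 7.05) for Wfdc17 (1, 16, 10 and 31 UMIs), 3.85 (1.97 to 5.73) for the inhibitory receptor gene Lilr4b (4, 7, 28 and 19 UMIs) and 3.43 (1.93 to 4.93) for Tnfrsf11a, which encodes the receptor RANK. The immunoglobulin light chain gene Igkc had 29, 10, 46 and 0 UMIs, a difference of at least 4.96. Igkc is among the fixed plasma cell markers. With Igha it was among the leading genes of a sub-cluster of 45, 20, 46 and 24 nuclei, so RNA of plasma cells is not excluded as its source. On the other side lay the vitamin D breakdown gene Cyp24a1 (72, 0, 17 and 22 UMIs; at most -2.39), Zswim5 (34, 0, 5 and 12 UMIs; at most -2.20), Zfp592 and Paip2. The 6 week library of MRL/lpr, in which 71.6% of the class held 3 or more proximal tubule markers, had the most UMIs of Cyp24a1, Zswim5, Zfp592 and Paip2. The sub-clusters richest in macrophage markers gave 25958, 11357, 40116 and 29477 of the 393962, 81687, 159346 and 195109 UMIs of the class. The differences of Ccl12, Wfdc17, Lilr4b and Tnfrsf11a may therefore rest on the makeup of the class, which was not tested.

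The mural-like class, the nearest to mesangial cells, allowed few comparisons, as 159 genes had enough UMIs. Of these 3 were at least 2-fold higher and 5 at least 2-fold lower in MRL/lpr at both ages, and 2 lay in opposite directions. Simulated libraries with no strain difference gave a mean of 0.2, but they hold counting error only and no difference in class makeup. Scaling by the median of ratios or by TMM gave 5 higher and 5 lower. Of the 3 higher genes 2 had higher CPM in the proximal tubule, with UMIs pooled over the 4 libraries. With such genes left out 0 were higher and 5 lower, as Ren1 then lay under 2-fold. With a minimum of 308 UMIs in all libraries 2 were higher and 0 lower. The renin gene Ren1 (ENSMUSG00000070645) was 2.42-fold (2.12 to 2.75) higher at 6 weeks and 2.03-fold (1.70 to 2.44) at 10 weeks, from 485, 461, 399 and 177 UMIs. The smaller of its log2 ratios was 1.02, and it was 0.97 with tubule-higher genes left out and 0.81 without nuclei that held 3 or more proximal tubule markers, so the 2-fold call is at its limit. Ren1 also led the cluster, and a sub-cluster led by it held 12, 15, 9 and 7 nuclei, or 42.9, 16.9, 18.0 and 14.3% of the class. The ferritin light chain gene Ftl1 was 2.57-fold (1.45 to 4.6) and 3.72-fold (1.68 to 9.32) higher, and Colec12 186-fold (32.5 to 7441) and 24.1-fold (7.94 to 119). Olfr1033 was at least 3.92-fold and at least 8.50-fold lower, the collagen gene Col12a1 4.21-fold (1.30 to 21.6) and 3.66-fold (1.76 to 8.32) lower, and the adhesion gene Sdk1 4.21-fold (1.30 to 21.6) and 3.14-fold (1.18 to 9.73) lower. Tafa1 (1, 28, 11 and 28 UMIs) and Cep112 (3, 29, 12 and 28) completed the lower genes. Sdk1 and Tafa1 led a sub-cluster that held 1, 29, 9 and 21 nuclei, or 3.57, 32.6, 18.0 and 42.9% of the class, so their ratios may rest on its makeup. In the mesangial activation list 4 genes could be compared, 1 higher and 2 lower at both ages, with medians of -0.85 (-1.63 to -0.20) and 0.12 (-0.46 to 0.80) at percentiles 31.4 and 63.6, and 0.20 and -0.29 without nuclei that held 3 or more proximal tubule markers, over 3 members that lay at -0.33 and -0.38 in all nuclei. The angiotensin receptor gene Agtr1a had 7, 44, 17 and 20 UMIs, the growth factor receptor gene Pdgfrb 9, 18, 19 and 11, and Acta2 9, 27, 9 and 11. The mesangial receptor list had 3 members (Igf1r, Pdgfrb and Itgb1), 1 higher and 1 lower at both ages, with medians of -0.87 (-1.92 to 0.02) and 0.61 (-0.44 to 1.28).

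Between ages, some genes of mural-like nuclei differed between the strains, while a sub-cluster led by H2-D1, Thbs1 and Mmp14 held 1, 12, 17 and 1 nuclei, or 3.57, 13.5, 34.0 and 2.04% of the class. A mesangial marker was seen on average in 25.8% of its nuclei, against 9.53 to 19.0% in the other sub-clusters. Igfbp7 had 18, 107, 144 and 38 UMIs, so that its age ratio was 3.1 (2.22 to 3.97) higher in MRL/lpr than in C57BL/6. The matrix gene Sparc (2, 24, 22 and 2 UMIs) differed by 5.11 (2.45 to 7.77), the protease inhibitor gene Serpine2 (11, 43, 45 and 13 UMIs) by 2.32 (1.04 to 3.61), Myo1d by 3.03 (0.90 to 5.16) and the integrin gene Itgb1 by 2.58 (0.53 to 4.62). These differences, and that of Igfbp7, may rest on the share of that sub-cluster, which was not tested. In the other direction lay the proximal tubule genes Slc5a12 (-2.13 (-3.56 to -0.69)) and Miox (-2.06 (-3.27 to -0.85)), with Pde1a and Frmd4b at -2.09 (-3.49 to -0.68) and -1.94 (-3.1 to -0.78). Of the mural-like nuclei 25, 7.87, 10.0 and 14.3% held 3 or more proximal tubule markers.

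In podocyte-like nuclei 30 genes were at least 2-fold higher and 46 at least 2-fold lower in MRL/lpr at both ages among 1238, with 21 in opposite directions. The mean was 1.35 in simulated libraries with no strain difference, which hold counting error only. With at least 500 genes per nucleus 17 of 226 genes were higher, 11 lower and 16 opposite. The ephrin receptor gene Epha6 (ENSMUSG00000055540) had 6, 0, 208 and 0 UMIs and was at least 2.41-fold and at least 81.9-fold higher. Lpin2, a lipid phosphatase gene, was 8.98-fold (4.77 to 18.7) and 6.71-fold (4.37 to 10.7) higher, and the carbonic anhydrase gene Car12 10.8-fold (3.89 to 41.9) and 17.7-fold (7.83 to 49.6). Colec12, the matricellular gene Ccn1, the phosphodiesterase gene Pde10a, the ephrin gene Efna5 and Smyd1 were also higher, with 369, 31, 590 and 58 UMIs for Colec12 and 55, 4, 101 and 22 for Pde10a. The nonclassical MHC class I genes H2-Q6 (0, 146, 1 and 198 UMIs) and H2-Q7 (2, 289, 2 and 378 UMIs) were close to 0 in MRL/lpr. Because these genes have near-identical copies that differ between haplotypes, their counts are uncertain. Lipoprotein lipase, Lpl, was 22.8-fold (6.03 to 193) and 12.7-fold (4.71 to 48.1) lower, the membrane fusion gene Nsf 9.86-fold (4.80 to 23.5) and 11.2-fold (6.09 to 23), Samd12 9.46-fold (3.83 to 30.3) and 8.82-fold (4.07 to 22.7), and Aebp1 4.77-fold (2.23 to 11.7) and 6.38-fold (3.39 to 13.3).

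Of 23 slit diaphragm and podocyte structure genes 9 were higher in MRL/lpr at 6 weeks and 17 at 10 weeks, 8 were higher and 5 lower at both ages, with medians of -0.16 (-0.26 to 0.00) at percentile 14.2 and 0.34 (0.22 to 0.44) at percentile 87.6, and -0.61 and 0.78 with at least 500 genes per nucleus. Podxl, which encodes the surface sialoprotein podocalyxin, was lower at both ages (-0.91 and -0.65; 370, 836, 551 and 1020 UMIs), and the phosphatase gene Ptpro higher (0.31 and 0.50). Magi2 lay at -0.21 and 0.37 and Dach1 at 0.02 and 0.20. Extracellular matrix genes had 3 members higher, 3 lower and 3 in opposite directions, with medians of -0.14 (-0.42 to 0.15) and 0.41 (-0.06 to 0.61). The basement membrane collagen genes Col4a3 (155, 215, 373 and 315 UMIs) and Col4a4 (102, 136, 243 and 180) were higher at 10 than at 6 weeks in MRL/lpr, by 0.72 (0.44 to 1.00) and 0.70 (0.36 to 1.05), and stood at 0.03 and -0.12 in C57BL/6. Timp3 had 87, 137, 118 and 243 UMIs and Sparc 38, 127, 101 and 134. All 7 mitochondrially encoded genes were at least 2-fold lower in MRL/lpr at both ages, among them mt-Nd4, mt-Cytb and mt-Co3 (39, 192, 25 and 280 UMIs), with medians of -2.03 (-2.41 to -1.78) and -3.22 (-3.84 to -3.00). Tubule RNA genes had medians of 1.77 (1.19 to 1.95) and -1.36 (-1.57 to -0.87) over 5 members, with Gpx3 at 1.77 and -1.36.

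MHC class II genes were higher in MRL/lpr endothelium-like nuclei at both ages, with 1 library per group. With at least 500 genes per nucleus the medians were -0.18 and 0.47 and Cd74 lay at -0.14 at 6 weeks, but no macrophage cluster formed there and the endothelium cluster was led by H2-Aa, H2-Eb1, Cd74 and C1qa, so it is another mixture. All 5 members were higher, with medians of 1.33 (0.83 to 2.27) at percentile 99.3 and 1.77 (1.36 to 2.38) at percentile 100. Cd74 (ENSMUSG00000024610) was 8.01-fold (5.79 to 11.3) higher at 6 weeks and 7.51-fold (6.2 to 9.16) at 10 weeks, from 272, 43, 570 and 130 UMIs, and H2-DMb1, which takes part in peptide loading, 8.70-fold (4.12 to 21.2) and 8.57-fold (4.56 to 17.5) higher. H2-Aa had 54, 27, 72 and 36 UMIs and H2-Ab1 43, 41, 92 and 62. All 5 were higher at 10 than at 6 weeks in both strains, with medians of 1.32 in MRL/lpr and 0.95 in C57BL/6. Nuclei with 3 or more proximal tubule markers made up 33.1, 1.62, 4.13 and 4.95% of the class, and without them the class II medians were 2.90 and 2.28 over 4 members. In all nuclei the same 4 members lay at 2.16 and 2.34. The macrophage gene C1qa was seen in 4 of 462, 2 of 1298, 4 of 509 and 1 of 869 of these nuclei (0.866, 0.154, 0.786 and 0.115%), so RNA of macrophages was not excluded as a source. Tubule RNA genes had medians of 2.01 (1.83 to 2.24) and -0.46 (-0.74 to -0.31) over 10 members, with Slc34a1 at 2.48 and -0.66.

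In all, 68 genes were at least 2-fold higher and 66 at least 2-fold lower in MRL/lpr endothelium-like nuclei at both ages among 5575, and 124 were apart in opposite directions; without nuclei that held 3 or more proximal tubule markers, 45 were higher, 60 lower and 10 opposite. Simulated libraries with no strain difference, which hold counting error only, gave a mean of 3.2. With UMIs pooled over the 4 libraries, 50 of the 68 higher genes had higher CPM in the proximal tubule, among them Colec12, Rims2, Cndp1 and Mt2. Of the 66 lower genes 3 did. MRL/lpr gave a larger part of the pooled UMIs in the proximal tubule than in endothelium-like nuclei, so part of this contrast may come from pooling. Mdga2 was 8.44-fold (3.56 to 24.4) and 20.8-fold (9.13 to 58.6) higher and the phosphodiesterase gene Pde8b 4.22-fold (1.95 to 10.1) and 25.7-fold (3.95 to 1082). H2-Q6, Nxpe4, Nxpe2 and Trim12a had 0 UMIs in both MRL/lpr libraries; Nxpe4 (0, 75, 0 and 67 UMIs) was at least 19.7-fold and at least 13-fold lower. The endosomal traffic gene Sft2d1 was 18.4-fold (6.94 to 68.8) and 24.5-fold (4.17 to 991) lower, Chst8 17.0-fold (4.42 to 145) and 16.9-fold (2.81 to 691), and the kinase gene Stk25 12.9-fold (4.16 to 64.7) and 22.2-fold (3.75 to 899). Rnaset2b (1, 85, 0 and 49 UMIs) has a near-identical copy, so its counts are uncertain.

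In the endothelial activation list 8 of 16 members were lower in MRL/lpr at both ages and none was higher. Its medians were -0.95 (-1.04 to -0.79) at percentile 0.01 and -0.15 (-0.27 to 0.06) at percentile 19.7. As fixed, the list also holds the endothelium markers Pecam1, Flt1, Kdr, Ehd3, Cdh5, Tek and Plvap, so these medians do not measure activation alone. The growth factor receptor gene Flt1 (-1.02 and -0.53) and Plvap (-1.03 and -0.18), which forms the diaphragms of fenestrated endothelium, were lower at both ages, and Eng (-0.36 and 0.20) and Tek (-0.37 and 0.27) at 6 weeks. Type I interferon genes had 3 of 18 members higher and 5 lower at both ages, with medians of -0.79 (-0.91 to -0.44) and 0.41 (0.09 to 0.60); the antiviral gene Rsad2 lay at -1.21 and -0.92, Bst2 at -0.37 and 0.33, Sp100 at -0.85 and 0.07, and Ifi27 at -1.1 and -0.25. Without nuclei that held 3 or more proximal tubule markers, the medians at 6 and 10 weeks were -0.04 and -0.20 for the activation list and 0.09 and 0.54 for type I interferon genes.

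The 6 classes outside the main comparisons were summarised by counts. At least 2-fold higher and lower in MRL/lpr at both ages were 88 and 96 of 7311 genes in distal convoluted tubule-like nuclei, 77 and 78 of 6351 in principal cell-like nuclei, 64 and 59 of 4399 in intercalated cell-like nuclei and 56 and 55 of 4809 in thick ascending limb-like nuclei. Fibroblast-like nuclei had 26 and 47 of 2633, and parietal epithelium-like nuclei 23 and 16 of 1088. Opposite directions at the 2 ages were found for 2 genes in the parietal class, 6 to 13 in the tubule classes and 32 in fibroblast-like nuclei.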

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

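The macrophage RNA, depth, hour of collection and UMI minimum tests below were set before the values they use were seen, and those on chromosomes, on cytoplasmic RNA, on nuclei outside the proximal tubule and on doublets were chosen after. The comparison of macrophage genes with the interferon gamma list was added after the result of the macrophage RNA test was seen. None of the differences between groups in this part was tested, because each group is 1 library.

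Some shares went different ways with age in the 2 strains. The age ratio of the mural-like share in MRL/lpr was 3.00 times that in C57BL/6 (1.72 against 0.571), a difference that was not tested; with a common minimum of 308 UMIs the strain ratio of that share at 6 weeks was 0.612, against 0.332. For fibroblast-like nuclei it was 3.54 times (1.43 against 0.404), also not tested.

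Other lists had strain ratios that differed between the ages, none of which was tested. In the proximal tubule, the median log2 strain ratio at 10 weeks minus that at 6 weeks was -1.72 for mitochondrially encoded genes (0.39 and -1.33) and -0.70 for cytoplasmic ribosomal protein genes (0.26 and -0.44). In macrophage-like nuclei it was 1.39 for resident macrophage genes, 1.51 for MHC class II genes, 2.00 for interferon gamma genes and -0.61 for tubule RNA genes. Podocyte-like nuclei had -3.13 for tubule RNA genes (1.77 and -1.36). Endothelium-like nuclei had 1.21 for type I interferon genes (-0.79 and 0.41) and -2.47 for tubule RNA genes (2.01 and -0.46). Without tubule-marker nuclei the medians at 6 and 10 weeks were 0.09 and 0.54 for type I interferon genes in endothelium-like nuclei. In macrophage-like nuclei they were 0.28 and 0.58 for class II, 0.33 and 0.66 for interferon gamma over 3 members (-0.74 and 0.90 for the same members in all nuclei), and -0.15 and 0.25 for resident genes over 8 (-1.22 and 0.49). The tubule RNA lists cannot be judged in this way, because the nuclei were left out for such genes.

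Single genes stood out by an age ratio that went opposite ways in the strains. In macrophage-like nuclei the log2 age ratio in MRL/lpr minus that in C57BL/6 was 3.43 for Tnfrsf11a (1.67 against -1.76) and -4.08 for Paip2 (-1.79 against 2.29). For genes with 0 UMIs in 1 library it was at least 4.96 for Igkc (1.97 against at most -2.99) and at most -2.20 for Zswim5 (-1.46 against at least 0.74). In mural-like nuclei it was 5.11 for Sparc (2.58 against -2.54), 3.1 for Igfbp7 (2.37 against -0.72), 2.32 for Serpine2 (1.39 against -0.93) and -1.94 for Frmd4b (-1.08 against 0.86). These differences were not tested and may rest on the makeup of the macrophage-like and mural-like classes. UMIs of the 4 Y-linked genes, 4 in C57BL/6 6 weeks, were seen in libraries whose labels name females, and this was not tested.

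The interferon gamma genes of the proximal tubule could come from macrophage RNA, from a difference in depth, from a variant at 1 locus, or from more interferon response in the tubule of MRL/lpr. The list lay at a median log2 of -2.19 (-2.48 to -1.75) in proximal tubule over macrophage-like nuclei of MRL/lpr 10 weeks, below the bound of -1 set in advance for macrophage RNA, while the macrophage genes C1qa, C1qb, C1qc, Lyz2 and Ctss had strain ratios in the proximal tubule of -0.14 at 6 and 1.00 at 10 weeks, so this test cannot tell. The added comparison speaks against macrophage RNA as the main source, because these genes lay at -8.60, far below the list, where 1 source would keep both at 1 ratio. Thinning to 500 UMIs left the median at 10 weeks at 1.58, against 1.78, above the bound set in advance. This cannot exclude depth, because CPM ratios are already scaled to the class sum and random thinning changes little in them. Members at least 2-fold higher at both ages lay on 7 chromosomes, so a single cis locus does not explain it. RNA of lymphocytes, variants that act on many genes, and disease were not tested and remain open.

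The clock genes in MRL/lpr 10 weeks may reflect another hour of collection or less cytoplasmic RNA in that library. The clock shift is the log2 ratio of evening genes minus that of morning genes. From 6 to 10 weeks in MRL/lpr it was 4.29 (3.96 to 4.67) in proximal tubule (-2.17 in C57BL/6). It was above 1 in 4 of 4 other tubule classes without their tubule-marker nuclei, as another hour of collection would give. In C57BL/6 these classes went both ways. The shift there was -1.91 in thick ascending limb, -2.54 in intercalated cell, 1.09 (0.18 to 2.19) in distal convoluted tubule and 0.56 (-0.76 to 1.70) in principal cell-like nuclei. The classes of a library thus did not all move together in C57BL/6. In proximal tubule 5 clock genes were at least 2-fold higher and 6 at least 2-fold lower at 10 than at 6 weeks in MRL/lpr. The 5 higher genes passed the bound set against less cytoplasmic RNA after the data were seen. This count cannot exclude that source, because CPM of RNA kept in the nucleus rises when cytoplasmic RNA falls. The hour of collection of the mice is not stated in the labels. A different clock in diseased mice was not tested.

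The low endothelium share of MRL/lpr at 6 weeks could come from the higher UMI minimum of that library, from more proximal tubule nuclei, from removed doublets, or from fewer endothelial cells. With a common minimum of 308 UMIs the share ratio at 6 weeks was 0.935, above the bound of 0.8 set in advance, so the minimum fits as a source. With tubule-marker nuclei left out as well it was 0.668 (0.575 to 0.775) at 6 weeks, so how much the minimum accounts for stays open. At 10 weeks these ratios were 0.561 (0.470 to 0.668) and 0.575 (0.477 to 0.691). Over nuclei outside the proximal tubule the ratio was 0.551 (0.494 to 0.613). This interval lay below 0.8, the bound for this source, but spanned the lower bound set against it. More proximal tubule nuclei thus did not account for the whole difference in these libraries, and how much they did cannot be told. Keeping doublets gave 0.392, so their removal did not cause it. Fewer endothelial cells in the tissue remain untested.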

How the results depend on the processing

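Tests here are comparisons of settings, of which the common UMI minimum, tubule-marker nuclei left out, macrophage sub-clusters and tubule-higher genes left out were chosen after the data were seen. No replicate numbers pair the libraries. Strains were set side by side within age, and a fit with age as a block, which would leave 1 residual degree of freedom, was not run. A value within the counting interval of the main result was called kept or stayed, even with another sign where that interval spans 0. It was called turned if its sign changed and that interval excludes 0, and otherwise moved. These intervals are wide for genes with few UMIs. Counts of genes were judged by a fixed fold around the main count. Genes that could no longer be compared were left out. Kept were 763 values of named strain ratios, 90 of age ratios and 181 of strain differences of age ratios, while 17, 0 and 3 moved and 1, 0 and 0 turned. Of list medians 473 stayed, 71 moved and 8 turned among lists not leading and 114, 18 and 2 among leading ones; shares stayed in 74, moved in 10 and turned in 5; counts stayed in 48 and moved in 22. Shallow nuclei limit the analysis: mural and podocyte classes had 159 and 1238 genes with enough UMIs, against 11789 in the proximal tubule. With 500 genes per barcode, no macrophage, fibroblast or mural cluster formed and the endothelium cluster mixed with macrophage genes. Clustering each library on its own left no mural cluster named in MRL/lpr 6 weeks. Values below are strain ratios of shares, counts of genes at least 2-fold apart in the same direction at both ages, and median log2 strain ratios; the cause was not tested except that stricter or looser UMI minima compare fewer or more genes.

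With 500 genes per barcode, share ratios at 6 and 10 weeks were 0.951 and 1.06 for proximal tubule, 1.62 and 1.88 for podocyte, and 3.04 and 0.725 for endothelium; 28 podocyte genes (main 76) were counted. Slit diaphragm medians were -0.61 and 0.78, endothelium class II -0.18 and 0.47, and Cd74 in endothelium at 6 weeks -0.14, in the mixed cluster. Each library clustered on its own gave a proximal tubule share ratio at 6 weeks of 1.35.

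A common minimum of 308 UMIs gave share ratios at 6 weeks of 1.21 for proximal tubule, 2.76 for macrophage, 0.612 for mural, 0.935 for endothelium and 0.274 for fibroblast. Counts were 2 in mural (2 higher and 0 lower, main 3 and 5) and 80 in endothelium (main 134), where 137 genes lay in opposite directions (main 124). Endothelium class II medians were 2.36 and 2.63.

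Without nuclei holding 3 or more proximal tubule markers, share ratios at 6 weeks were 0.932 for macrophage and 0.264 for endothelium, and counts were 13 of 536 compared genes in macrophage (2.43%; main 108 of 4323, 2.5%) and 5 of 107 in mural (main 8 of 159), so fewer genes were compared. At 6 weeks macrophage interferon gamma was 0.33, class II 0.28 and resident genes -0.15, mesangial activation in mural 0.20 (-0.29 at 10 weeks, over 3 of 4 members, which lay at -0.33 and -0.38 in all nuclei), slit diaphragm 0.0330, endothelium type I interferon 0.0938, class II 2.90 and tubule RNA -0.00239. Podocyte tubule RNA at 10 weeks was 0.43; these tubule RNA values follow from the choice of nuclei. Sub-clusters richest in macrophage markers gave a share ratio of 1.39 at 6 weeks, 16 of 226 genes, resident medians of -0.50 and 0.00998, and class II medians of -0.22 and 0.30, so at 6 weeks class II lay on another side than without tubule-marker nuclei.

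At least 20 UMIs gave counts of 339 in macrophage (main 108), 45 in mural (8), 219 in podocyte (76) and 348 in endothelium (134), and a resident median at 10 weeks of -0.0656. At least 200 UMIs gave 248 in proximal tubule (main 490), 9 in macrophage, 1 in mural, 19 in podocyte and 18 in endothelium, a resident median at 10 weeks of 0.64 and endothelium type I interferon at 10 weeks of -0.21. Thinning to 500 UMIs left out 2020, 3965, 3148 and 3603 nuclei. Counts were then 30 in macrophage, 1 in mural, 38 in podocyte and 15 in endothelium, where 60 genes lay in opposite directions. Medians were then -0.29 for fatty acid oxidation in proximal tubule at 6 weeks, -0.59 and 0.72 for resident genes, 0.00475 for macrophage tubule RNA at 10 weeks and 0.0246 for slit diaphragm at 6 weeks.

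With doublets kept, resident medians were -0.52 and 0.0273 and the slit diaphragm median at 10 weeks 0.45. Leaving out genes at higher CPM in the proximal tubule gave counts of 53 in macrophage, 5 in mural (0 higher and 5 lower) and 77 in endothelium. Scaling by the median of ratios or TMM moved mural strain ratios at 6 weeks by 0.15 and 0.29 and no other main class by over 0.1. These scalings were not run in the classes outside the main comparisons.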

Other observations

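The comparison with tubule RNA in this part was added after the data were seen, and the genes, sub-clusters and lists below were chosen after the data were seen.

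A few genes differed between the strains in many classes. Colec12 was at least 2-fold higher in MRL/lpr at both ages in 11 classes and Stam2 in 10. Bbs9, Rims2 and Zfp949 were higher and Rnaset2b lower in 7 classes each. Nuclei of other classes also held UMIs of proximal tubule genes, so the CPM of a gene in a class, as a share of that in the proximal tubule, was set against that of 14 proximal tubule markers in both MRL/lpr libraries. The 95% interval of Colec12 lay above the highest marker in 7 of 10 other classes and that of Stam2 in 4 of 9, among them all 4 other tubule classes. In macrophage, endothelium and parietal classes neither did so, nor did Stam2 in podocyte and fibroblast classes, and there tubule RNA is not excluded; in macrophage-like nuclei Colec12 stood at 94.3 and 67.4%, with markers up to 104 and 73.6%. RNA of other tubules was not compared. At least 2-fold higher at both ages in 1 or more classes were 594 genes, of which 10 were so in 5 or more, and 545 were lower, of which 10 in 5 or more.

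Parietal epithelium-like nuclei, which line the capsule of the glomerulus, made up 0.924, 0.985, 1.84 and 1.37% of the kept nuclei in MRL/lpr 6 weeks, C57BL/6 6 weeks, MRL/lpr 10 weeks and C57BL/6 10 weeks. The share at 10 weeks was 1.99 times (1.52 to 2.64) that at 6 weeks in MRL/lpr and 1.39 times (1.05 to 1.85) in C57BL/6. With MRL/lpr 10 weeks clustered on its own, a cluster of 166 nuclei with 3 enriched parietal markers, none of them leading, stayed unnamed. Chemokine and leukocyte adhesion genes of this class were higher in MRL/lpr at both ages in 4 of 6 members, with medians of 1.25 (0.44 to 2.06) and 0.57 (0.17 to 1.06), and were higher at 10 than at 6 weeks by 1.03 in MRL/lpr and 1.13 in C57BL/6. Of the parietal nuclei 27.5, 11.1, 22.9 and 9.09% held 3 or more proximal tubule markers, so these genes may rest in part on tubule RNA. Fibroblast-like nuclei of MRL/lpr had higher type I interferon genes in 5 of 7 members, with medians of 0.68 (0.08 to 1.01) and 0.84 (0.11 to 1.39). Their extracellular matrix genes lay at -0.35 (-0.53 to -0.17) at 6 weeks and 0.43 (0.26 to 0.77) at 10 weeks over 27 members.

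Genes for signals from macrophages to mesangial cells, the subject named in the series title, went both ways in macrophage-like nuclei: 4 of 11 members were higher and 4 lower in MRL/lpr at both ages, with medians of -0.30 (-0.58 to 0.24) and 0.04 (-0.30 to 0.29). Spp1 (391, 46, 98 and 95 UMIs, in the same order of libraries) was higher at both ages (0.80 and 0.34), and Apoe (900, 402, 976 and 768) lay at -1.11 and 0.64. Spp1 was also higher in the MRL/lpr proximal tubule at both ages. Of the macrophage-like nuclei 71.6, 31.8, 35.7 and 35.2% held 3 or more proximal tubule markers, so tubule RNA is not excluded as a source of Spp1. In the sub-clusters richest in macrophage markers Apoe had 11519, 18139, 16153 and 15402 CPM.

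Within the macrophage-like class, a sub-cluster with the T and NK cell genes Ms4a4b, Nkg7, Trbc1 and Cd3g held 22, 9, 30 and 26 nuclei in the same order of libraries, and one with the dendritic cell genes Wdfy4, Flt3, Clec9a and Xcr1 held 15, 8, 25 and 10. In the mural-like class, nuclei led by Ren1 numbered 12, 15, 9 and 7 and those led by Myh11 7, 27, 11 and 14. Mitochondrially encoded genes were lower in MRL/lpr at 10 weeks in the tubule classes, with medians of -0.87 in thick ascending limb, -1.07 in distal convoluted tubule, -0.85 in principal and -1.25 in intercalated cell-like nuclei.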
